A study of Mus musculus with 22 samples.

How the data were processed

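Gene expression was measured with microarrays in lung metastases of mice that had received mammary epithelial cells by tail-vein injection. The injected cells were NMuMG cells, a mouse mammary gland epithelial line, carrying ErbB2 together with either PGC-1alpha or a control vector. The mice were then given phenformin for 1 week, or PBS. Per the labels, the lungs were perfused with embedding solution, metastases were isolated by laser capture microdissection, and 10 ng of RNA per sample was amplified and labelled with a kit for very small amounts.

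The deposited values are log2 array signals that the authors had already normalised, with 1 value per probe set and array. Per the submitters' processing notes the software was oligo. Its version, the method of background correction and the method of normalisation are not stated. The table held 28815 probe sets, of which 6609 were controls (5222 negative, 1324 positive and 63 spike-in) and 22206 were not. Array medians over the probe sets that are not controls lay between 6.55 and 6.64, and 25th percentiles between 5.01 and 5.23. The share of positive against negative control pairs in which the positive control was brighter (area under the curve, AUC) was 0.902 to 0.938 per array. The number of arrays limits the precision of every value. Another deposited table was not used here, because its 22 columns carry bare numbers that match no sample name. The comparison with that table, chosen before the data were examined, was therefore not run.

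Gene symbols came from the deposited annotation through the Entrez identifier: 19572 probe sets had 1 symbol, 0 had several and 2634 had none. No symbol changed when symbols were updated against the reference gene table. Where a gene had more than 1 probe set, which was so for 55 genes, the probe set with the highest mean was used, giving 19505 genes. A gene was tested if it lay above the array's 25th percentile in at least 5 arrays, which left 15545 genes. The files name no genome build, so no coordinates are given. The reference gene table (assembly GRCm38.p6) served only for names and for which genes neighbour each other. It held all 15545 symbols and placed 15514 of them on the chromosome that the probe set names.

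The 22 arrays fall into 4 groups by injected line and treatment. They hold 6 PGC-1alpha arrays under phenformin, 6 PGC-1alpha arrays under PBS, 5 control arrays under phenformin and 5 control arrays under PBS. The labels give neither dates nor batches, and they do not say how many animals stand behind the arrays. The p-values therefore measure the spread between samples and may be too small if samples share an animal. The labels number the samples within each group, but nothing states that equal numbers belong together, so no pairing was used.

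All 4 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes; 18 residual and 5.67 prior degrees of freedom). Group means were compared for each line and treatment, for the interaction, and averaged over treatments or lines. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes are called passed, and p values are two-sided. Errors of log2 differences are standard errors (SE) from the fit, and group levels are means with SD. Where a group's mean for a named gene lay below the mean of its arrays' median negative controls, a fold is given as a lower bound, with each value raised to at least its array's median negative control, a rule added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

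The comparisons, tests, named-gene rule, gene lists and most alternative settings were chosen before the data were examined. There were 24 gene lists: complex I, complexes II to IV, ATP synthase, citrate cycle, fatty acid oxidation, mitochondrial biogenesis with known PGC-1alpha partners, mitochondrial ribosome, glycolysis, hypoxia response, integrated stress response, unfolded protein response, folate cycle and purine synthesis, cholesterol synthesis, fatty acid synthesis, antioxidant defence, glutamine and proline metabolism, cell cycle, interferon response, inflammatory cytokines, epithelial junction and keratin, mesenchymal transition, immediate early genes, lysosome and autophagy, and cytosolic ribosome. There were 13 marker lists: alveolar type 2, alveolar type 1, club and ciliated, endothelial, fibroblast and smooth muscle, mesothelial, macrophage, neutrophil, T and NK, B and plasma, erythroid and cardiac muscle cells, and mammary tumour epithelium. The lists share few genes: 12 of their 637 genes stand in more than 1 list. Members were matched by symbol, then by synonym. Atp5pb and Ero1a were matched by an older name. Gpi1, Eno1, Loxl2 and Srebf1 were left out because their only synonym match was a different gene's own symbol, a rule set after the data were seen. The B and plasma list kept 4 tested genes and the erythroid list 3, so these lists say little about those cells.

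Each list was compared with all other genes by camera with a preset correlation of 0.01, and p values were adjusted over the 37 lists within each comparison. The tests were repeated with the correlation estimated per list, and with fry, which asks only whether the list's own genes move. The count of list members passing is given over all genes and adjusted over the list alone. A score is the mean over a list's genes of their log2 signal, each gene centred on its mean over all arrays. The normal lung score is the mean of the alveolar type 2, alveolar type 1, club and ciliated, and endothelial scores. The immune score is the mean of the macrophage, neutrophil, T and NK, and B and plasma scores. Differences of single scores were tested by an exact permutation of cell lines within treatments (213444 rearrangements, two-sided), with intervals at 95 percent confidence.

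Named genes are Ppargc1a, which encodes PGC-1alpha, and Erbb2, the 12 genes that rose most and the 12 that fell most per simple comparison (5 for the interaction and for averaged contrasts), and up to 4 members with the smallest p per list. Where fewer than 5 genes passed, the 5 with the smallest p are named. Predicted genes, clones, small RNAs and olfactory or vomeronasal receptor genes were left out of the naming but not of the counts.

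The alternatives were no filter, a filter at each array's median, quantile normalisation again, centring each array on its median, eBayes with trend and robust, array weights, the replicate number as a block, all probe sets, the normal lung score or the immune score as a covariate, a 1.5-fold minimum, only the groups compared, and each array left out in turn. Cyclic loess between arrays, the control AUC as a covariate, and leaving out the 4 arrays of lowest weight together were added after the data had been seen. Data were simulated with the spread of the 15545 genes, each gene drawn independently, so the false calls leave out any correlation between genes. On these data the fit recovered 45 of 100 genes changed 1.5-fold and 97 of 100 changed 2-fold for the cell lines under PBS, with 7 false calls. For the cell lines under phenformin it recovered 51 and 87, with 7 false calls. For phenformin in control metastases it recovered 41 and 92, with 12 false calls, and in PGC-1alpha metastases 47 and 97, with 8 false calls. For the interaction it recovered 16 and 65, with 0 false calls.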

Results

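Transcript levels were measured in lung metastases taken by laser capture microdissection from mice injected with ErbB2-carrying NMuMG mammary epithelial cells. The cells were labelled as overexpressing PGC-1alpha, a coactivator that drives mitochondrial biogenesis, or as carrying the control vector. Mice received phenformin, a biguanide that inhibits respiratory complex I, or PBS. The 22 arrays comprised 5 control metastases under PBS, 5 control metastases under phenformin, 6 PGC-1alpha metastases under PBS and 6 PGC-1alpha metastases under phenformin. Median log2 signal per array was 6.55 to 6.64, the AUC of positive against negative controls was 0.902 to 0.938, and the median SD of a gene within a group was 0.252. How many animals stand behind the arrays is not given.

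Ppargc1a, the gene introduced into the PGC-1alpha line, had a log2 signal of 7.54 ± 0.60 (SD, n = 5) in control and 8.90 ± 0.37 (n = 6) in PGC-1alpha metastases under PBS. Under phenformin it had 8.04 ± 0.39 (n = 5) and 8.64 ± 0.79 (n = 6). The lines did not overlap under PBS (highest control array 8.24, lowest PGC-1alpha array 8.46) but did under phenformin, where PGC1a_phenformin 6 had 7.65 and control_phenformin 4 had 8.67. Whether its probe set detects the introduced sequence is not known. Erbb2, the oncogene carried by both lines, lay at 8.04 ± 0.25 and 8.33 ± 0.22 under PBS, and at 7.91 ± 0.12 and 8.32 ± 0.34 under phenformin. For Erbb2 too it is not known whether the probe set detects the introduced sequence.

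**Figure D1:**
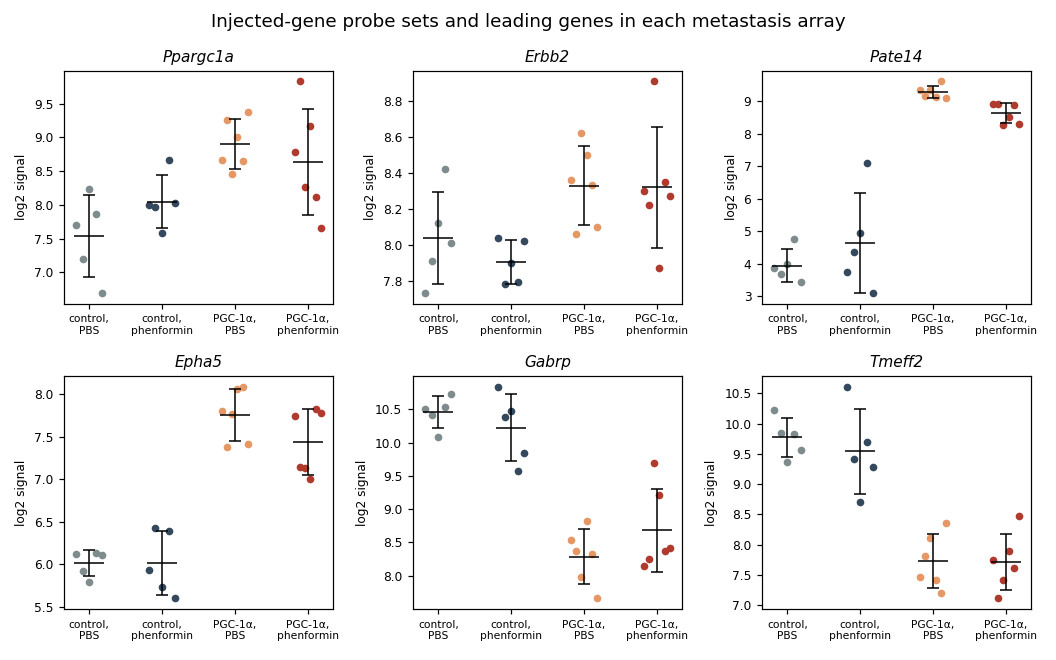
Log2 signal of Ppargc1a, Erbb2, Pate14, Epha5, Gabrp and Tmeff2 in each of the 22 arrays (points), with the mean and SD of each of the 4 groups. Pate14 lay near 9.28 in PGC-1alpha and 3.95 in control metastases under PBS.

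PGC-1alpha and control metastases were compared first in mice given PBS. PGC-1alpha goes with the injected line in all arrays, so other differences between the lines cannot be told apart from it. Pate14, of a family of small secreted proteins best known from prostate and testis, rose at least 23.3-fold (adjusted p = 7.2e-08), counting control values below the median negative control of their array as equal to it. It went from 3.95 ± 0.50 (n = 5) to 9.28 ± 0.19 (n = 6), and 7 of all 10 control arrays lay below their median negative control (4.61 to 5.05). Epha5, an ephrin receptor kinase, rose 3.33-fold (SE 0.18 on the log2 scale, adjusted p = 1.37e-05), and the cartilage proteoglycan gene Acan rose 3.36-fold (SE 0.23, adjusted p = 0.000268). Gabrp, a GABA receptor subunit of secretory epithelia, fell from 10.45 ± 0.24 to 8.28 ± 0.41 (log2 change −2.17, SE 0.26, adjusted p = 8.68e-05), and Tmeff2, a transmembrane protein with follistatin-like domains, fell from 9.77 ± 0.33 to 7.72 ± 0.45 (−2.05, SE 0.27, adjusted p = 0.000268). Ppargc1a itself rose 2.57-fold (log2 1.36, SE 0.31, adjusted p = 0.0198). Erbb2 did not pass (0.29, SE 0.15, adjusted p = 0.307).

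In all, 455 of 15545 genes passed under PBS, 188 higher and 267 lower in PGC-1alpha metastases, and 2799 had an unadjusted p under 0.05 where 777 would by chance. Other large rises were in Scg2, a secretogranin of neuroendocrine granules (1.98), Serpinb2 (1.79), the prolactin-family gene Prl2c5 (1.64), the glycerol kinase gene Gk2, Tmem132c (1.53), the milk protein gene Csn3 (1.48), Pate8 (at least 1.62-fold, from below the negative controls) and Clca3b (1.47). The largest falls besides Gabrp and Tmeff2 were in Dmbt1, a mucosal scavenger protein (−2.24), the apolipoprotein gene Apob (−1.75), the adhesion receptor gene Adgrg2 (−1.71), Fhl1 (−1.59), Ifit1bl1 (−1.48), the fatty acid receptor gene Ffar4 (−1.41), Gstm1 (−1.39), the granzyme gene Gzma (−1.38), the extracellular superoxide dismutase gene Sod3 (−1.33) and the myelin protein gene Pmp22 (−1.30). Their adjusted p lay between 0.000316 for Pate8 and 0.0378 for Gzma. Quantile normalisation of the values again gave 253 genes higher and 249 lower.

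Among the gene lists, 12 of 37 shifted under PBS by the test with a preset correlation, 1 upward and 11 downward, and 0 did with an estimated correlation (smallest adjusted p = 0.169). The list alone, tested by fry, moved for 3: neutrophil markers (adjusted p = 0.00276), inflammatory cytokines (adjusted p = 0.00759) and alveolar type 1 markers (adjusted p = 0.0336). Neutrophil markers had a median of −0.48 over 8 genes (adjusted p = 0.000609; adjusted p = 0.169 with an estimated correlation), and 4 of them were lower over all genes and 4 adjusted over the list alone. They included the chemokine receptor gene Cxcr2 (−1.24, SE 0.18), the calprotectin genes S100a8 (−1.07) and S100a9 (−0.91), and the colony-stimulating factor receptor gene Csf3r (−0.71). The inflammatory cytokines were lower too, with a median of −0.25 over 20 genes (adjusted p = 0.000409; adjusted p = 0.169 with an estimated correlation). Over all genes 3 were lower, Ccl20, Cxcl5 (−0.81) and Il1a (−0.87), and 8 were lower adjusted over the list alone. Interferon response genes had a median of −0.34 over 24 genes, with 1 lower over all genes, Ifit1, and 3 adjusted over the list alone (adjusted p = 0.0015; adjusted p = 0.706 with an estimated correlation).

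Complex I and mitochondrial ribosome transcripts were slightly lower in PGC-1alpha metastases, while the other mitochondrial lists given here did not shift. Complex I had a median of −0.18 over 36 genes (adjusted p = 0.00595; adjusted p = 0.706 with an estimated correlation). Over all genes 2 were lower, Ndufb4 (−0.49) and Ndufb2 (−0.47), and adjusted over the list alone 2 were higher and 5 lower. The mitochondrial ribosome had a median of −0.13 over 40 genes (adjusted p = 0.0164; adjusted p = 0.616 with an estimated correlation), with 1 lower over all genes, Mrpl13 (−0.51), and 0 by limma adjusted over the list alone. Complexes II to IV (median 0.00, adjusted p = 0.997), ATP synthase (−0.12, adjusted p = 0.125), the citrate cycle (0.04, adjusted p = 0.823) and the biogenesis list (0.04, adjusted p = 0.968) did not shift. The unfolded protein response list had a median of −0.12 over 17 genes (adjusted p = 0.0164; adjusted p = 0.616 with an estimated correlation). Its chaperone cofactor gene Sdf2l1 was lower over all genes (−0.46; 1 gene), and 2 genes were lower adjusted over the list alone. Cytosolic ribosomal protein genes shifted upward, with a median of 0.10 over 25 genes of which 0 passed in limma, over all genes or adjusted over the list alone (adjusted p = 0.0193; adjusted p = 0.706 with an estimated correlation). Single members of lists without a shift also passed: the succinate dehydrogenase gene Sdhb (−0.54), the citrate cycle gene Mdh2 (0.40), the serine synthesis gene Phgdh (0.65), the pyrimidine synthesis gene Umps (−0.66), Sod1 (−0.30) and the AP-1 gene Fosl1 (0.69). Ndufb4, Sdf2l1, Umps and Sod1 lie on chromosome 16, whose 490 tested genes were lower as a group (median −0.14 under PBS; 41 lower, 0 higher).

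Lung tissue marker lists were also lower in PGC-1alpha metastases under PBS. Alveolar type 1 markers had a median of −0.36 over 9 genes, 1 of them lower over all genes (Emp2, on chromosome 16) and 2 adjusted over the list alone (adjusted p = 0.00269; adjusted p = 0.446 with an estimated correlation). Alveolar type 2 markers had −0.25 over 11 genes, with 0 passing over all genes and 4 lower adjusted over the list alone (adjusted p = 0.00791; adjusted p = 0.616 with an estimated correlation). Endothelial markers had −0.36 over 14 genes, with 0 over all genes and 1 adjusted over the list alone (adjusted p = 0.002; adjusted p = 0.616 with an estimated correlation). Club and ciliated cell markers had −0.80 over 8 genes, with 0 over all genes and 3 lower adjusted over the list alone (adjusted p = 0.0324; adjusted p = 0.706 with an estimated correlation). T and NK cell markers were also lower (1 gene over all genes, Gzma at −1.38, a granzyme of cytotoxic lymphocytes, and 2 adjusted over the list alone; adjusted p = 0.0339, and adjusted p = 0.616 with an estimated correlation). The mannose receptor gene Mrc1 (0.93, SE 0.18) and the mesothelin gene Msln (0.59) were the marker genes that passed upward.

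The count of 455 fell to 48 with the normal lung score as a covariate, 28 with the immune score, 86 without the 4 arrays of lowest weight, 237 with only the groups compared, and to 191, 202, 206, 213 or 302 without control_PBS 5, control_PBS 2, PGC1a_PBS 1, PGC1a_PBS 3 or PGC1a_PBS 2. Ppargc1a no longer passed under the lung covariate (0.681, adjusted p = 0.357), the immune covariate (1.11, adjusted p = 0.276), without the 4 arrays (1.13, adjusted p = 0.127), or without control_PBS 2 or control_PBS 5. Of the 44 other results for named genes under PBS, 24 were lost without at least 1 array, though not those of Pate14, Epha5, Acan, Gabrp or Tmeff2. Lost without control_PBS 2 alone were Scg2 (1.81), Tmem132c (1.45) and Clca3b (1.38), and without control_PBS 5 alone Gstm1 (−1.19), Sod3 (−1.18), Cxcl5 (−0.77) and Msln (0.54). Serpinb2 was lost without control_PBS 2 or 5 (1.54 each), Ifit1bl1 without PGC1a_PBS 1 (−1.45) or control_PBS 2 (−1.41) or 3 (−1.38), and Ccl20 without PGC1a_PBS 3 (−1.09) or control_PBS 4 (−1.01) or 5 (−0.94). Each lost without any 1 of 5 to 18 arrays were Dmbt1, Gzma, Sdhb, Mdh2, Umps, Il1a, Ndufb4, S100a9, Ifit1, Sod1, Emp2, Sdf2l1, Ndufb2 and Mrpl13.

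The 12 lists that shifted under PBS became 3 with the normal lung score as a covariate, 7 with the immune score and 7 without the 4 arrays of lowest weight. Of the 12 shifts, 7 held with each array left out in turn. The mitochondrial ribosome (median −0.129) was lost without control_PBS 2 (−0.080) and had −0.081 without PGC1a_PBS 2. Also lost were the unfolded protein response without control_PBS 4, and the cytosolic ribosome without PGC1a_PBS 6, control_PBS 1 or control_PBS 5. Club and ciliated markers were lost without PGC1a_PBS 4, 5 or 6 or control_PBS 2, 4 or 5, and T and NK markers without PGC1a_PBS 1, 2 or 6 or control_PBS 1 or 2. The T and NK median of −0.175 became −0.091 without control_PBS 2, −0.292 without control_PBS 5, −0.317 without PGC1a_PBS 3 and −0.322 without PGC1a_PBS 4. The complex I median went from −0.178 to −0.094 without control_PBS 5, and that of the cytokines from −0.246 to −0.379 without control_PBS 4.

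**Figure D2:**
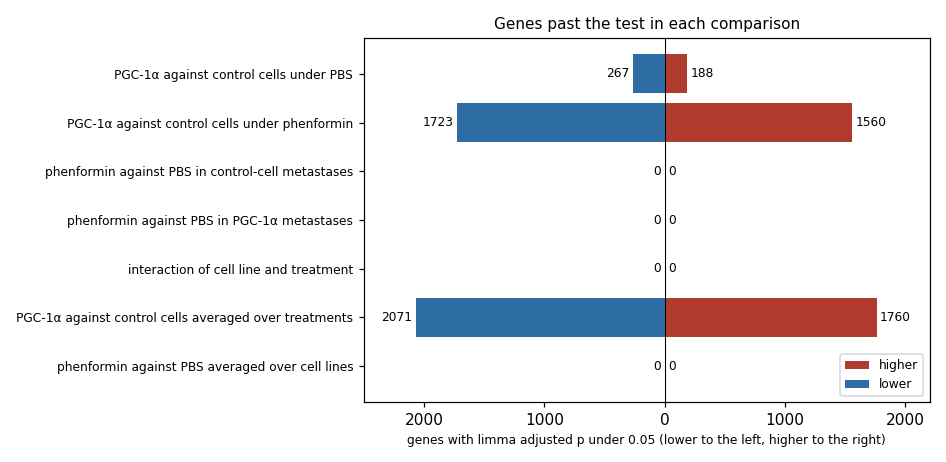
Number of genes higher and lower (bars) at adjusted p under 0.05 in each of the 7 comparisons, of 15545 genes tested. The cell lines differed in 455 genes under PBS and in 3283 under phenformin, while the comparisons of phenformin with PBS gave 0.

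The same contrast of cell lines was made in mice given phenformin. Pate14 again rose most, from 4.65 ± 1.53 (n = 5) to 8.62 ± 0.31 (n = 6), at least 10.1-fold against the negative controls (adjusted p = 2.49e-05). The array control_phenformin 4 stood at 7.09, and without it the control mean was 4.04 and the rise at least 13.8-fold. Epha5 rose 2.67-fold, from 6.02 ± 0.38 to 7.44 ± 0.38 (SE 0.18, adjusted p = 0.00028), and the B-cell transcription factor gene Ebf1 rose 2.06-fold (SE 0.18, adjusted p = 0.00135). Adgrg2 fell from 8.63 ± 0.26 to 6.47 ± 0.86 (−2.16, SE 0.32, adjusted p = 0.00057), and Olr1, a receptor for oxidised lipoprotein on myeloid and endothelial cells, fell from 8.93 ± 0.48 to 6.89 ± 0.47 (−2.04, SE 0.29, adjusted p = 0.000377). The basophil protease gene Mcpt8 fell from 8.80 ± 0.38 to 7.29 ± 0.35 (−1.51, SE 0.19, adjusted p = 0.000213) and the chemokine gene Ccl3 fell by 1.86 (SE 0.40, adjusted p = 0.0046). Ppargc1a did not pass here (0.59, SE 0.31, adjusted p = 0.166), nor did Erbb2 (0.41, adjusted p = 0.0526).

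Under phenformin 3283 genes passed, 1560 higher and 1723 lower, and 5770 had an unadjusted p under 0.05. Further rises were in Clca3b (1.65), Scg2 (1.48), Gk2 (1.42), Tmem132c (1.32), Pate8 (at least 1.32-fold), Acan (1.20), the cornified envelope gene Sprr1a (0.96), the exocytosis gene Cadps (0.92) and the neuronal gene Slitrk5 (0.94). Further falls were in Dmbt1 (−2.03), Tmeff2 (−1.83), Prelid2 (−1.66), Fhl1 (−1.55), Gabrp (−1.54), Samsn1 on chromosome 16 (−1.51), the purinergic receptor gene P2ry13 (−1.45) and the carboxylesterase gene Ces2g (−1.44). Of the genes that passed under PBS, 80 were also higher and 195 also lower under phenformin, and 0 passed in opposite directions in limma. If the tests were independent, 18.9 and 29.6 would overlap by chance. Both tests use the same estimate of spread per gene, so they are not fully independent. Of the 455 genes, 438 had the same sign under phenformin. Across all genes the log2 differences under PBS and phenformin, from different arrays, had a correlation of 0.54 (Spearman 0.51); genes are not independent replicates.

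The split by direction depends on scaling: centring each array on its median gave 1112 higher and 2203 lower, quantile normalisation again 1337 higher and 1096 lower, and cyclic loess 1035 higher and 1304 lower. With the immune score as a covariate 731 genes passed. Of the 111 results for named genes under phenformin, 35 were lost without at least 1 array, among them Scg2 without control_phenformin 1 (1.26).

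Complex I, ATP synthase and mitochondrial ribosome lists were lower in PGC-1alpha metastases under phenformin, while complexes II to IV did not shift. In this contrast the 3109 brightest of all genes had a median of −0.13 and the 3109 dimmest 0.177, a trend that the list test does not account for. Complex I had a median of −0.21 over 36 genes (adjusted p = 0.00141; adjusted p = 0.835 with an estimated correlation). Over all genes 1 was higher and 11 lower, and adjusted over the list alone 1 was higher and 16 lower, among them Ndufb5 (−0.59), Ndufb3 (−0.53), Ndufa2 (−0.48) and Ndufa9 (−0.64). The mitochondrial ribosome had −0.26 over 40 genes, with 9 lower over all genes and 11 adjusted over the list alone (adjusted p = 0.00141; adjusted p = 0.804 with an estimated correlation). Within it Mrpl13 fell 2.05-fold (SE 0.14, adjusted p = 0.00028). ATP synthase had −0.18 over 16 genes (adjusted p = 0.0309; adjusted p = 0.835 with an estimated correlation). Over all genes 5 were lower, and adjusted over the list alone 1 was higher and 7 lower, including Atp5o on chromosome 16 (−0.60) and Atp5c1 (−0.55); the shift was lost without PGC1a_phenformin 6, control_phenformin 1 or control_phenformin 3. Complexes II to IV (median −0.03 over 25 genes, adjusted p = 0.348) had 4 members lower over all genes and 4 adjusted over the list alone: Sdha (−0.55), Sdhb (−0.56), Sdhd (−0.53) and Uqcrfs1 (−0.41). The Sdha call was lost without any 1 of 6 arrays (−0.54 to −0.46): PGC1a_phenformin 1, 2 or 6 or control_phenformin 2, 4 or 5. The list of mitochondrial biogenesis genes and known PGC-1alpha partners had −0.12 over 27 genes (adjusted p = 0.224). Over all genes, and adjusted over the list alone, 1 was higher, Ppargc1b, and 6 lower, including the mitochondrial transcription factor gene Tfb2m (−1.11, SE 0.26), Tomm22 (−0.52) and the polymerase subunit gene Polg2 (−0.64).

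Neutrophil, cytokine and interferon transcripts were lower under phenformin as well, while macrophage, T and NK, and B and plasma markers did not shift. Neutrophil markers had a median of −0.65 over 8 genes (adjusted p = 0.0118; adjusted p = 0.544 with an estimated correlation). Over all genes 5 were lower, and 5 adjusted over the list alone, with S100a8 (−1.04), Cxcr2 (−0.93), Csf3r (−0.49) and the collagenase gene Mmp8 (at least 1.88-fold, to below the negative controls). Inflammatory cytokines had −0.41 over 20 genes, with 7 lower over all genes and 10 adjusted over the list alone (adjusted p = 0.00175; adjusted p = 0.544 with an estimated correlation), including the cytokine genes Il1a (−1.18), Cxcl5 (−0.88) and Ccl7 (−0.83). Interferon response genes had −0.44 over 24 genes, with 4 lower over all genes and 2 adjusted over the list alone (adjusted p = 0.00171; adjusted p = 0.835 with an estimated correlation): Oasl2 (−0.75), Irgm1 (−0.65), Usp18 (−0.64) and Ddx58 (−0.85). The interferon shift was lost without control_phenformin 1, as was the call of Irgm1 (−0.55). Usp18 was lost without any 1 of 7 arrays (−0.67 to −0.42), PGC1a_phenformin 2 to 6 or control_phenformin 1 or 5, and Ddx58 without any 1 of 8 (−0.93 to −0.66), PGC1a_phenformin 2, 3, 4 or 6 or control_phenformin 1, 3, 4 or 5. These 6 lists were the only ones of 37 to shift by the test with a preset correlation, 0 shifted with an estimated correlation, and 9 moved by fry.

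Other metabolic lists held members that changed without a shift of the list. The citrate cycle (median 0.02, adjusted p = 0.692) had 2 higher, Suclg2 (0.52) and Sucla2 (0.56), and 1 lower, Dld (−0.62), by both counts. Fatty acid oxidation (−0.14, adjusted p = 0.348) had 1 higher and 2 lower over all genes, and 2 higher and 4 lower adjusted over the list alone, led by the trifunctional protein gene Hadhb (−0.64). The integrated stress response (−0.05 over 27 genes, adjusted p = 0.751) had 5 higher and 2 lower over all genes, and 5 higher and 4 lower adjusted over the list alone. Within serine synthesis Psat1 fell (−0.86, SE 0.16) while Phgdh rose (0.50; not passing at 0.39 without control_phenformin 2), and Cebpb rose (0.51). The folate cycle and purine list (−0.10, adjusted p = 0.495) had 1 higher and 3 lower over all genes and 1 higher and 4 lower adjusted over the list alone, with Dhodh (0.63) and Umps on chromosome 16 (−0.83) moving apart. Fatty acid synthesis (−0.28, adjusted p = 0.305) had 1 higher, Acacb (0.50), and 4 lower over all genes, and 2 and 4 adjusted over the list alone. Glycolysis (−0.12, adjusted p = 0.27; 1 lower over all genes, Pfkm, lost without any 1 of 6 arrays, 0 adjusted over the list alone) and the hypoxia response (−0.23, adjusted p = 0.268; 0 by limma on both counts) did not shift. The cell cycle list (−0.16 over 36 genes, adjusted p = 0.0949) had 1 higher and 7 lower over all genes, and 2 and 7 adjusted over the list alone, among them the mitotic kinesin gene Kif20a (−0.91) and the replication gene Mcm4 on chromosome 16 (−0.55).

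Further lists without a shift were cholesterol synthesis (median −0.14, adjusted p = 0.27), where Sc5d fell by 0.47, and antioxidant defence (adjusted p = 0.296), where the mitochondrial peroxidase gene Prdx3 fell (not passing at −0.56 without control_phenformin 2). Glutamine and proline metabolism (adjusted p = 0.969) and the unfolded protein response (−0.16, adjusted p = 0.223; Pdia6 lower at −0.45, not passing at −0.38 without control_phenformin 5) did not shift. The same held for epithelial junction and keratin genes (−0.16, adjusted p = 0.348; Krt19 lower at −0.50, lost without any 1 of 6 arrays), for mesenchymal transition (−0.04, adjusted p = 0.692; Snai2, on chromosome 16, lower at −0.59, lost without any 1 of 7) and immediate early genes (0.05, adjusted p = 0.624; Fosl1 higher at 0.58). Lysosome and autophagy (0.03, adjusted p = 0.969) and the cytosolic ribosome (adjusted p = 0.831) did not shift either. Lung marker lists without a shift were alveolar type 2 (−0.21, adjusted p = 0.232), alveolar type 1 (−0.19, adjusted p = 0.232), club and ciliated (0.22, adjusted p = 0.706) and endothelial (−0.39, adjusted p = 0.0848). Other marker lists without a shift were fibroblast and smooth muscle (0.04, adjusted p = 0.969), mesothelial (−0.22, adjusted p = 0.969), macrophage (−0.14, adjusted p = 0.334), T and NK (−0.11, adjusted p = 0.667), B and plasma (0.32, adjusted p = 0.27), erythroid (−0.18, adjusted p = 0.692), cardiac muscle (−0.18, adjusted p = 0.969) and mammary tumour epithelium (−0.12, adjusted p = 0.664). Within them the vascular gene Eng (−1.22, SE 0.34), the scavenger receptor gene Msr1 (−0.86), the alveolar gene Aqp5 (−0.82) and Lamp3 on chromosome 16 (−0.85) fell, and Cd8a (0.71, lost without any 1 of 7 arrays) and Slc4a1 (0.63) rose. Over all genes 1 was lower in cholesterol synthesis and in the unfolded protein response, 3 in antioxidant defence, and 1 in the epithelial list. Glutamine and proline metabolism had 2 higher and 1 lower, mesenchymal transition 1 and 2, immediate early genes 3 and 1, and lysosome and autophagy 2 and 1. Adjusted over the list alone these counts were the same except for antioxidant defence (2 lower), glutamine and proline metabolism (2 higher, 3 lower), and the epithelial and mesenchymal lists (0 by limma). Of the markers, 2 alveolar type 2, 1 alveolar type 1, 2 endothelial and 2 macrophage genes were lower, 2 B and plasma genes and 1 erythroid gene higher, and 1 mesothelial and 1 T and NK gene higher and 1 lower each, over all genes and adjusted over the list alone. Cardiac markers (1 higher) and mammary epithelium (1 lower) had genes over all genes but 0 by limma adjusted over the list alone. Median, mean and test differed in sign for glutamine and proline metabolism, lysosome and autophagy, fibroblast, erythroid and cardiac markers under phenformin. Under PBS they did for complexes II to IV, fatty acid oxidation, mitochondrial biogenesis, glycolysis, hypoxia, cholesterol synthesis, immediate early genes, B and plasma, and erythroid markers, and no list that shifted was among them.

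**Figure D3:**
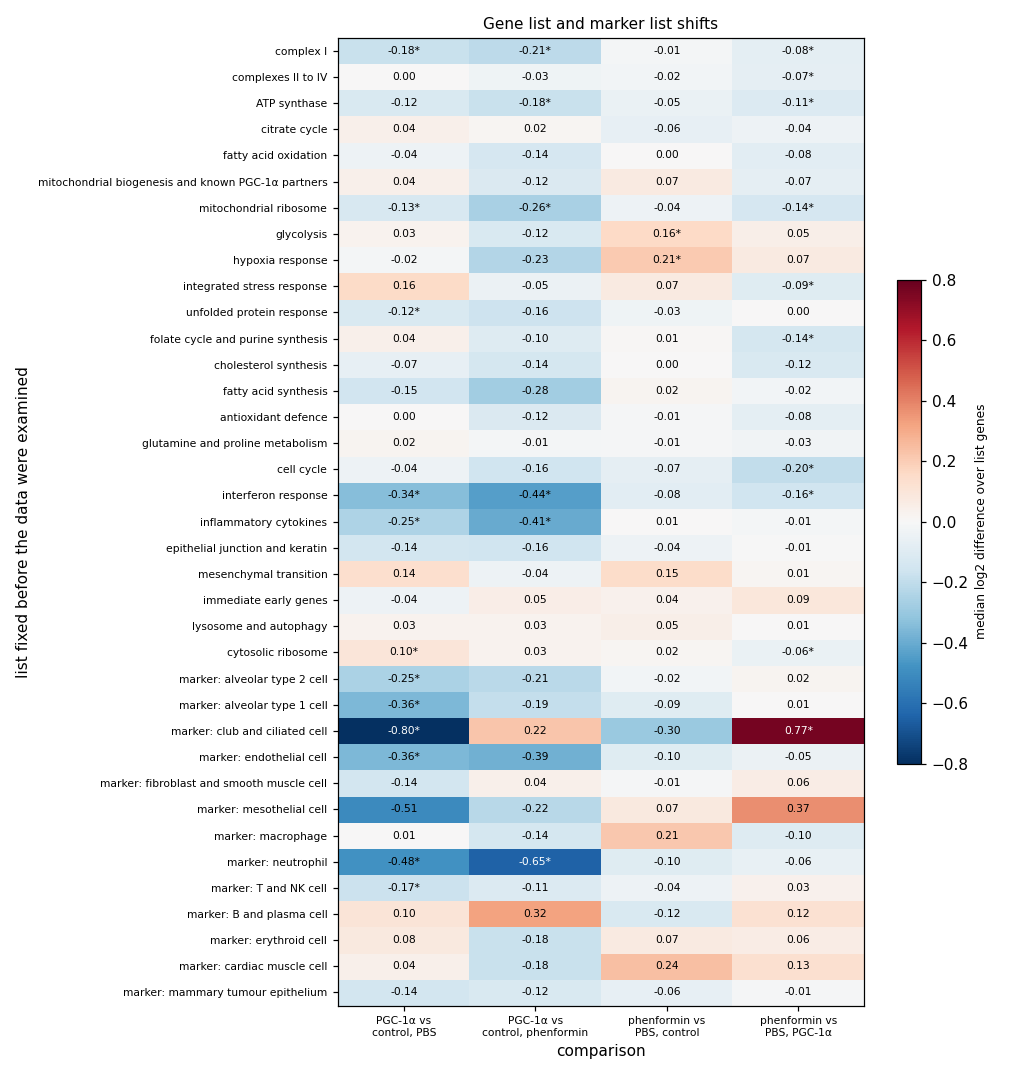
Median log2 difference of each of the 37 lists (lines of the heat map) in 4 comparisons (columns), with a star where the test with a preset correlation gave adjusted p under 0.05. Neutrophil markers were lower in PGC-1alpha metastases under PBS and under phenformin, and 0 of the starred shifts pass with an estimated correlation.

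The response to phenformin was read within each line, since biguanides act on the respiratory chain. In control metastases 0 of 15545 genes passed in limma, with 1498 at an unadjusted p under 0.05 and a smallest adjusted p of 0.188. The genes with the smallest p were the branched-chain ketoacid dehydrogenase kinase gene Bckdk (0.94, SE 0.18), the nucleotide sugar transporter gene Slc35d1 (1.23, SE 0.25), the chloride channel gene Clcn3 (0.66), Celf5 (−0.67) and Gpank1 (0.55), which lay at 7.65 ± 0.07 (n = 5) under PBS and 8.20 ± 0.06 (n = 5) under phenformin. Ppargc1a did not pass (0.50, adjusted p = 0.621). As groups, hypoxia response genes were higher under phenformin (median 0.21 over 19 genes, adjusted p = 0.0116; adjusted p = 0.936 with an estimated correlation) and so were glycolysis genes (0.16 over 19 genes, adjusted p = 0.0266; adjusted p = 0.936 with an estimated correlation). No member passed in limma over all genes or adjusted over the list alone. The members with the smallest p were Pdk1, which limits entry of pyruvate into the citrate cycle (0.91, SE 0.29, adjusted p = 0.312), the hexokinase gene Hk1 (1.20, SE 0.39, adjusted p = 0.316) and the prolyl hydroxylase gene P4ha1 (0.52, adjusted p = 0.433). By fry 0 lists moved, and under cyclic loess 0 lists passed; the 2 lists became 0 without control_phenformin 5, control_PBS 4 or control_PBS 5, 1 without control_PBS 2, and 4 without control_phenformin 1 or 2. Without control_phenformin 5 the glycolysis median was 0.10.

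In PGC-1alpha metastases phenformin also left 0 genes passing in limma, with 674 at an unadjusted p under 0.05, where 777 would be by chance, and a smallest adjusted p of 0.586. That gene was Psat1, which makes phosphoserine, with 8.70 ± 0.24 (n = 6) under PBS and 7.93 ± 0.25 (n = 6) under phenformin (−0.77, SE 0.15). Next came Fam131c (0.46), Exoc3 (−0.46), the lipid droplet gene Ldah (−0.45) and the glucocorticoid-induced gene Fkbp5 (−0.61), all with an adjusted p of 0.957. Cell cycle genes were lower as a group (median −0.20, adjusted p = 8.18e-06; adjusted p = 0.456 with an estimated correlation), with the mitotic genes Cenpe (−0.57, SE 0.17), Cdc20 (−0.47) and Ccna2 (−0.44) at the smallest p but not passing. Lists of the respiratory machinery were lower by small amounts. In this comparison the 3109 brightest of all genes had a median of −0.061 and the 3109 dimmest 0.063. The list test does not account for this trend, and complex I, complexes II to IV and the cytosolic ribosome lay near the level of the brightest genes. The mitochondrial ribosome had −0.14 (adjusted p = 1.76e-05), ATP synthase −0.11 (adjusted p = 0.00172) and complexes II to IV −0.07 (adjusted p = 0.0135), each at adjusted p = 0.456 with an estimated correlation. Complex I had −0.08 (adjusted p = 0.00234; adjusted p = 0.592 with an estimated correlation). The folate cycle and purine list (−0.14, adjusted p = 0.0347) and the integrated stress response (−0.09, adjusted p = 0.0442) were lower, each at adjusted p = 0.456 with an estimated correlation. So were interferon response genes (−0.16, adjusted p = 0.017) and the cytosolic ribosome (−0.06, adjusted p = 0.0303), each at adjusted p = 0.681 with an estimated correlation. Club and ciliated markers were higher (0.77, adjusted p = 1.76e-05; adjusted p = 0.456 with an estimated correlation), with the secretoglobin genes Scgb1a1 (2.17, SE 0.84) and Scgb3a2 (2.71, SE 1.25) far above the rest but not passing. Without PGC1a_phenformin 3 the median of these markers was 0.27. No member of any of these lists passed in limma over all genes, and adjusted over the list alone 1 did, Psat1 of the integrated stress response. By fry 0 lists moved, against 10 by the preset correlation, 5 passed under cyclic loess, and 16 passed without PGC1a_PBS 6. Of the 10 shifts, 5 held with each array left out in turn. That of complexes II to IV was lost without PGC1a_phenformin 5, and that of the folate and purine list without PGC1a_phenformin 2, 3 or 6 or PGC1a_PBS 1 or 5. The integrated stress response was lost without PGC1a_phenformin 4, 5 (median −0.061) or 6, PGC1a_PBS 1, 2 or 3 or control_PBS 1. Interferon was lost without PGC1a_phenformin 2, 3 or 4 or PGC1a_PBS 3 (−0.089) or 4, and its median was −0.245 without PGC1a_phenformin 5 and −0.305 without PGC1a_PBS 1. The cytosolic ribosome was lost without PGC1a_phenformin 4, 5 or 6 (−0.032) or PGC1a_PBS 1 or 2, and had −0.034 without PGC1a_PBS 6.

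Whether the lines responded differently was asked with the interaction of line and treatment. In limma 0 genes passed, 1724 had an unadjusted p under 0.05 and the smallest adjusted p was 0.173. The genes with the smallest p were Gpank1 (−0.87), the ubiquitin ligase gene Rnf150 (0.77), the lymphocyte adaptor gene Sla2 (0.83), Psat1 (−1.10) and the complex I subunit gene Ndufs1 (−0.93). For Ppargc1a the interaction was −0.77 (SE 0.44, adjusted p = 0.51), so its passing under PBS and not under phenformin is not shown to be a difference between treatments. No list passed (smallest adjusted p = 0.148, club and ciliated markers; 0.855 with an estimated correlation; 0.318 by fry), and by fry in either direction the integrated stress response did (adjusted p = 0.0181). Across genes, the phenformin effects in both lines had a correlation of −0.22 (Spearman −0.25), and genes are not independent replicates. Trends with brightness also ran in opposite directions. The 3109 dimmest genes had a median of −0.08 in control and 0.063 in PGC-1alpha metastases, the 3109 brightest 0.03 and −0.061. Such trends can give a negative correlation, so it does not show opposite responses of the lines. Leaving out PGC1a_phenformin 3 gave 2 genes and leaving out control_PBS 2 gave 1. Of the lists, 6 passed without control_phenformin 2, 2 without PGC1a_phenformin 6, 1 each without PGC1a_phenformin 2, PGC1a_PBS 3, control_phenformin 3 or control_PBS 3, and 4 without the 4 arrays of lowest weight.

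Averaged over treatments, which uses all 22 arrays, PGC-1alpha metastases differed from control metastases in 3831 genes (1760 higher, 2071 lower; 6066 at an unadjusted p under 0.05). The split by direction depends on scaling here too, with 1884 higher and 1633 lower after quantile normalisation again, 1406 and 2407 with each array centred on its median, and 1552 and 1889 after cyclic loess. Pate14 rose at least 15.3-fold (adjusted p = 8.23e-10), Epha5 rose by 1.58 on the log2 scale (SE 0.13, adjusted p = 9.8e-08), and Scg2 (1.73), Clca3b (1.56) and Gk2 followed. Tmeff2 fell by 1.94 (SE 0.19, adjusted p = 1.97e-06), and Dmbt1 (−2.13), Adgrg2 (−1.94), Gabrp and Fhl1 (−1.57) fell too. Ppargc1a rose 1.97-fold (log2 0.98, SE 0.22, adjusted p = 0.00321) and Erbb2 rose slightly (0.35, SE 0.11, adjusted p = 0.0193). The 10 lists that shifted were all lower, and 0 did with an estimated correlation. With each array left out in turn 7 held, while ATP synthase was lost without control_phenformin 3, the unfolded protein response without PGC1a_PBS 5, control_phenformin 5 or control_PBS 4, and alveolar type 2 markers without PGC1a_phenformin 4, PGC1a_PBS 6, control_phenformin 2 or 3 or control_PBS 1. Neutrophil markers (median −0.65, adjusted p = 0.00101) and inflammatory cytokines (−0.40, adjusted p = 0.00024) came closest, each at adjusted p = 0.193 with an estimated correlation. In this contrast the 3109 brightest of all genes had a median of −0.082 and the 3109 dimmest 0.096. The list test does not account for this trend. Complex I (−0.20, adjusted p = 0.000415), ATP synthase (−0.14, adjusted p = 0.0244), the mitochondrial ribosome (−0.18, adjusted p = 0.000674), the unfolded protein response (−0.18, adjusted p = 0.0302) and interferon response genes (−0.43, adjusted p = 0.00024) each had adjusted p = 0.67 with an estimated correlation. Endothelial (−0.39, adjusted p = 0.00423) and alveolar type 1 markers (−0.25, adjusted p = 0.0226) also had adjusted p = 0.67 with an estimated correlation, and alveolar type 2 markers (−0.21, adjusted p = 0.0302) adjusted p = 0.693 with an estimated correlation. Over all genes the cytokines had 9 lower and the neutrophil markers 5, and adjusted over the list alone the cytokines had 1 higher and 11 lower and the neutrophil markers 5 lower. Complex I had 1 higher and 15 lower by both counts, and the mitochondrial ribosome 11 lower over all genes and 15 adjusted over the list alone. With the normal lung score as a covariate 2036 genes passed and Ppargc1a did not (0.522, adjusted p = 0.0971). With the immune score 397 genes passed and Ppargc1a did not (0.739, adjusted p = 0.202).

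Averaged over lines, phenformin changed 0 genes in limma (616 at an unadjusted p under 0.05; smallest adjusted p = 0.971, for Kctd13 at −0.41). The next were the protocadherin genes Pcdhb17 (0.48) and Pcdhb4 (0.32), the cell cycle target Cdca7l (−0.49) and the macrophage gene Lacc1 (−0.52). By the test with a preset correlation 6 lists were higher and 5 lower. The higher lists were hypoxia (0.16, adjusted p = 0.000676), glycolysis (0.11, adjusted p = 0.00123), mesenchymal transition (0.09, adjusted p = 0.021), immediate early genes (0.08, adjusted p = 0.0391), club and ciliated markers (0.60, adjusted p = 0.0122) and cardiac markers (0.18, adjusted p = 0.0127). The lower lists were cell cycle (−0.15, adjusted p = 1.73e-05), mitochondrial ribosome (−0.07, adjusted p = 0.00123), ATP synthase (−0.07, adjusted p = 0.0122), interferon (−0.12, adjusted p = 0.0314) and complex I (−0.05, adjusted p = 0.0391). With an estimated correlation complex I and interferon had adjusted p = 0.697 and the others adjusted p = 0.618, and by fry 0 moved. Of the 11 shifts, those of the mitochondrial ribosome, glycolysis (0.069 without control_phenformin 5), hypoxia and cell cycle lists held with each array left out. Cardiac markers were lost without control_phenformin 3 (median 0.026), PGC1a_phenformin 3 or control_PBS 3, club and ciliated markers without PGC1a_phenformin 3 (0.308), control_phenformin 3 or control_PBS 3, and ATP synthase without control_phenformin 2 or 4. Mesenchymal transition was lost without any 1 of 8 arrays: PGC1a_phenformin 2 or 6, PGC1a_PBS 5, control_phenformin 2 or 5, or control_PBS 1, 2 or 5. Complex I was lost without any 1 of 13 arrays: PGC1a_phenformin 2, 3, 5 or 6, PGC1a_PBS 2, 4 or 6, control_phenformin 1, 2 (−0.033), 4 or 5, or control_PBS 2 (−0.035) or 5. Interferon was lost without any 1 of 11: PGC1a_phenformin 2, 3 (−0.071) or 4, PGC1a_PBS 3 (−0.062) or 4 (−0.074), control_phenformin 2 (−0.052), 3, 4 or 5, or control_PBS 3 or 5 (−0.076). It held at −0.194 without PGC1a_PBS 1 and −0.210 without control_phenformin 1. Immediate early genes were lost without any 1 of 13: PGC1a_phenformin 3 (0.038), 5 or 6, PGC1a_PBS 1 (0.050), 2 or 3, control_phenformin 1 (0.045), 2 (0.051), 3 or 5 (0.024), or control_PBS 1, 3 or 5 (0.051). They held at 0.045 without PGC1a_PBS 5. The number of lists was 6 without PGC1a_phenformin 3 or control_phenformin 2, and 7 without control_phenformin 5, control_PBS 3 or control_PBS 5.

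**Figure D4:**
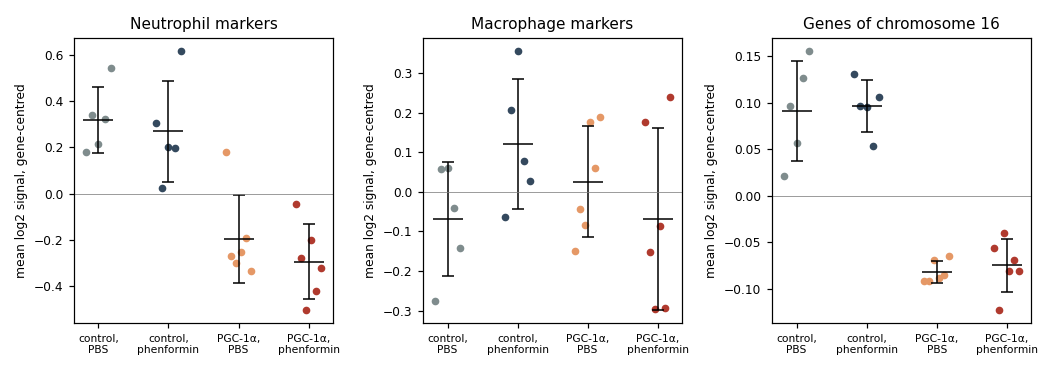
Neutrophil, macrophage and chromosome 16 scores (mean of gene-centred log2 signal) in each of the 22 arrays (points), with the mean and SD of each group. All PGC-1alpha arrays lay at or below −0.04 on the chromosome 16 score and all control arrays at or above 0.021.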

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

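The tests of array signal quality, of a phenformin response that differs between lines, of neutrophil against macrophage and other host markers, of gene density and of chromosome windows were chosen only after the result they test was seen, as were cyclic loess and the control AUC covariate.

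Far more genes separated the lines under phenformin (3283) than under PBS (455). In PGC-1alpha against control metastases under phenformin the 3109 dimmest genes had a median difference of 0.177 and the 3109 brightest −0.13, so a brightness-dependent difference between arrays was tested. After cyclic loess 2339 genes still passed under phenformin, against 503 under PBS, and with the control AUC as a covariate 2704 did, which argues against brightness and array signal quality as the whole cause. A response to phenformin that differs between the lines stays open: 1724 genes had an unadjusted p under 0.05 in the interaction test, where 777 would by chance, and 0 passed in limma. Of 100 splits of single arrays between the lines, only the real one gave as many genes under phenformin (3283, highest other 592). The same held under PBS (455, highest other 54). Chance placement of independent arrays is thus unlikely for both counts. The labels do not give the number of animals, and these splits cannot exclude differences between animals if arrays share an animal.

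Neutrophil markers were lower in PGC-1alpha metastases, with an averaged score difference of −0.542 (95% interval −0.705 to −0.379, exact permutation p = 1.41e-05). Of the 8 genes, S100a8 lay at 9.97 ± 0.23 and 9.55 ± 0.22 in control and at 8.91 ± 0.51 and 8.51 ± 0.43 in PGC-1alpha metastases, under PBS and phenformin; 3 of them did not pass averaged over treatments, Mmp9 (0.07, SE 0.22), Camp (0.02, SE 0.10) and Retnlg (−0.14, SE 0.18). After cyclic loess the difference was −0.551 (−0.708 to −0.393), and neutrophil minus macrophage scores differed by −0.494 (−0.726 to −0.262, exact permutation p = 0.00044). The loess value argues against a brightness trend. The other argues against a lower share of all host cells alike only if both marker scores follow cell share equally, which was not tested. With the normal lung score as covariate the difference was −0.577 (−0.779 to −0.374). That score mostly follows its club and ciliated part, with an SD of 1.52 in PGC-1alpha metastases under phenformin, against 0.18 for alveolar type 1. The covariate therefore cannot decide whether less alveolar or endothelial tissue was captured. Endothelial (−0.461), alveolar type 1 (−0.262), T and NK (−0.252) and alveolar type 2 (−0.238) scores fell too. Neutrophil scores fell further than alveolar type 1 (−0.281, exact permutation p = 0.00731), T and NK (−0.29, exact permutation p = 0.0346) and alveolar type 2 scores (−0.304, exact permutation p = 0.00453). Neutrophil minus endothelial scores did not pass (−0.0807, −0.403 to 0.242, exact permutation p = 0.593), so a joint loss of some host cells stays open. The groups overlap (lowest control score 0.026, highest PGC-1alpha score 0.182), and fewer neutrophils in the captured PGC-1alpha metastases, or lower expression of these genes within cells, tumour cells included, may explain it, as hypotheses that these arrays cannot separate.

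Genes of chromosome 16, picked after several of them were seen among the genes that changed and the medians of all chromosomes had been looked at, were lower in PGC-1alpha metastases, with a median of −0.144 over 490 genes (158 lower, 31 higher) and a score difference of −0.173 (−0.202 to −0.143, exact permutation p = 4.69e-06), and every PGC-1alpha array (highest −0.04) lay below every control array (lowest 0.021). After cyclic loess the difference was −0.182 (−0.209 to −0.155). Of 10000 gene sets matched on signal and local gene density, 0 percent had a median as low (lowest −0.05). These values argue against brightness or local gene density as the whole cause. With the score of chromosomes 12, 13 and 18 as covariate the difference was −0.134 (−0.174 to −0.094). This argues against a trend shared with these chromosomes pooled as the whole cause. The pool joins chromosome 18 with chromosomes 12 and 13, whose averaged medians were less low (−0.031 and −0.077). The covariate therefore cannot decide whether chromosome 16 shares a trend with chromosome 18 alone. A difference in copy number between the injected lines stays open and unsupported: 16 of 19 windows of neighbouring genes had a median below 0 under both treatments, but shuffling the gene order gave 13 to 19, so the count restates that most of these genes were lower, and DNA was not measured. Chromosome 18 was low too, with a median of −0.121 averaged and −0.171 under phenformin (−0.156 for chromosome 16). By these medians the pattern is not particular to chromosome 16. Of the 14 windows of chromosome 18, 13 had a median below 0 under both treatments. Its gene order was not shuffled, so this count adds no support. Chromosome 18 was not compared with matched gene sets. A response of these genes to PGC-1alpha itself is untested.

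For the averaged difference between lines, only the real one of 100 splits gave as many genes (3831, highest other 5). Chance placement of independent arrays is thus unlikely, but differences between animals are not excluded if arrays share an animal. For the interaction 1724 genes had an unadjusted p under 0.05 (1445 after cyclic loess), and 2 of 100 splits were as large, counting the real one. The highest other, 2046, exceeds it and 0 genes passed in limma, so chance is unlikely there but not excluded. Chance cannot be excluded for phenformin in control metastases (1498 such genes, highest other 2371; 16 of 100 splits as large), in PGC-1alpha metastases (674, highest other 1702; 25 of 100) or averaged over lines (616, highest other 1607; 77 of 100).

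Single arrays stood apart in 26 of 384 groups of values checked, where chance would give about 1 in 20, or 19.2. The figure given for each is the array's gap to its nearest neighbour as a share of the group's range. Among control metastases under PBS, control_PBS 1 had Ces2g at 8.15 against 8.95 to 9.10 in the others (0.845), a citrate cycle score of −0.18 against 0.02 to 0.10 (0.742) and a control AUC of 0.902 against 0.93 (0.892). Control_PBS 5 had Ifit1bl1 at 5.75 against 6.82 to 7.15 (0.768) and Lacc1 at 7.52 against 6.44 to 6.68 (0.783). Control_PBS 2 had Fam131c at 4.91 against 5.23 to 5.31 (0.798), control_PBS 3 had Pcdhb17 at 6.70 against 6.05 to 6.23 (0.734), and control_PBS 4 had an inflammatory cytokine score of −0.03 against 0.21 to 0.23 (0.93).

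Among control metastases under phenformin, control_phenformin 5 had Gstm1 at 7.90 against 9.32 to 9.70 (0.793), Celf5 at 5.74 against 5.24 to 5.34 (0.8) and an inflammatory cytokine score of 0.57 against 0.15 to 0.23 (0.818). Control_phenformin 3 had Cdca7l at 7.35 against 8.07 to 8.22 (0.837), a B and plasma cell score of 0.12 against −0.24 to −0.15 (0.742) and a cardiac muscle score of 1.59 against −0.33 to −0.03 (0.846). Control_phenformin 4 had Pcdhb17 at 6.55 against 6.87 to 6.95 (0.79) and an alveolar type 1 score of −0.14 against 0.15 to 0.24 (0.769). Control_phenformin 1 had Serpinb2 at 8.14 against 10.19 to 10.63 (0.826).

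Among PGC-1alpha metastases under PBS, PGC1a_PBS 5 had Slitrk5 at 7.54 against 6.34 to 6.62 (0.764) and Bckdk at 7.88 against 7.03 to 7.30 (0.684). PGC1a_PBS 4 had Ccl3 at 7.99 against 6.69 to 7.02 (0.747), PGC1a_PBS 1 had a neutrophil score of 0.18 against −0.34 to −0.19 (0.723), and PGC1a_PBS 3 had a club and ciliated score of 0.78 against −1.27 to −1.04 (0.885). Under phenformin, PGC1a_phenformin 1 had Ffar4 at 5.75 against 6.75 to 7.29 (0.646) and a score for complexes II to IV of 0.04 against −0.12 to −0.06 (0.632). PGC1a_phenformin 2 had a fatty acid synthesis score of −0.25 against −0.07 to 0.02 (0.676), and PGC1a_phenformin 3 had a mammary tumour epithelium score of 0.82 against −0.28 to −0.04 (0.782).

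Probe sets with no gene symbol, which no comparison of genes used, also separated the lines. Of 1817 tested, 49 passed under PBS (35 higher, 14 lower), 425 under phenformin (317 higher, 108 lower) and 488 averaged over treatments (347 higher, 141 lower). These are 2.7, 23.4 and 26.9 percent, against 2.9, 21.3 and 24.9 percent of the other probe sets, and limma found 0 in any comparison of phenformin with PBS or in the interaction.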

How the results depend on the processing

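Cyclic loess, the control AUC covariate and leaving out the 4 arrays of lowest weight (control_PBS 1 and 5, control_phenformin 2 and 3) were chosen after the data had been seen. The cause was not tested for any change given here, except that a 1.5-fold minimum can only lower a count. Both scores differed between the lines under PBS: the normal lung score was 0.23 ± 0.27 in control and −0.33 ± 0.10 in PGC-1alpha metastases, the immune score 0.12 ± 0.08 and −0.07 ± 0.07. These covariates can therefore also remove part of the difference between lines. No result for a named gene reversed. Of 272 calls of named genes, 193 were lost with the immune covariate, 89 without the 4 arrays, 82 with the normal lung covariate, 46 with quantile normalisation again, 43 with cyclic loess, 31 with the AUC covariate, 21 with the replicate block and 14 or fewer with the other settings; leaving out 1 array lost 469 of 5984 such values. Of the 20 named results that had not passed, 1 did with an array left out (Gpank1 in the interaction, without PGC1a_phenformin 3). Without at least 1 array, 24 of 44 calls were lost under PBS, 35 of 111 under phenformin and 14 of 117 averaged.

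For PGC-1alpha against control cells under PBS, 455 genes became 48 (42 shared) with the lung covariate, 28 (26 shared) with the immune covariate, 86 (71 shared) without the 4 arrays, 237 with only the groups compared, 299 at 1.5-fold, and 191 to 491 with 1 array left out (191, 202, 206, 213 and 302 without control_PBS 5, control_PBS 2, PGC1a_PBS 1, 3 and 2). Under phenformin 3283 became 731 (673 shared) with the immune covariate, 1137 at 1.5-fold and 2189 to 3617 with 1 array left out. Averaged, 3831 became 2036 with the lung covariate, 397 with the immune covariate, 559 at 1.5-fold and 3176 to 4268 with 1 array left out. Calls under PBS and phenformin that were tested kept their sign in the 12 settings where this was counted (not with 1 array left out or only the groups compared), and of the averaged ones 3821 of 3831 did with the immune covariate. The comparisons of phenformin with PBS gave 0 genes with each array left out, and the interaction 0 to 2 (1 without control_PBS 2, 2 without PGC1a_phenformin 3).

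Ppargc1a under PBS went from 1.36 to 0.681 with the lung covariate, 1.11 with the immune covariate, 1.13 without the 4 arrays, and 1.149 to 1.536 with 1 array left out (not passing without control_PBS 2, 1.275, or control_PBS 5, 1.149). Under phenformin it ranged from 0.355 to 0.79. Averaged, it went to 0.522 with the lung covariate, 0.739 with the immune covariate and 0.858 to 1.075 with 1 array left out.

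Of 51 list shifts 27 held with each array left out in turn. In the same direction but no longer passing were all 51 with an estimated correlation, 33 by fry, 27 with the immune covariate, 21 with the lung covariate, 16 with cyclic loess, 15 without the 4 arrays and 5 with the replicate block. Besides these, 1 shift was lost under each covariate by turning upward: the mitochondrial ribosome under PBS with the immune covariate (adjusted p = 0.991), and club and ciliated markers under PBS with the lung covariate (adjusted p = 0.107). The 12 lists under PBS became 0 with an estimated correlation, 3 by fry, 3 with the lung covariate, 7 with the immune covariate, 7 without the 4 arrays and 9 to 12 with 1 array left out. The 6 under phenformin became 0, 2 with the immune covariate, and 4 to 8. The 2 for phenformin in control metastases became 0 by estimated correlation, fry and cyclic loess, and 0 to 4. The 10 in PGC-1alpha metastases became 0 by estimated correlation and fry, 5 with cyclic loess, and 7 to 16. The interaction had 4 without the 4 arrays and 0 to 6. The 10 averaged became 0 with an estimated correlation, 5 with either covariate, and 8 to 11. The 11 for phenformin averaged over lines became 0 by estimated correlation and fry, 5 with the immune covariate, 6 without the 4 arrays, and 6 to 12.

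The samples share only a number: with it as a block 381, 3218 and 3706 genes passed under PBS, under phenformin and averaged. Of 31 pairs with equal numbers 7 had a correlation above 0.1 (−0.189 to 0.312), and 9 of 22 arrays correlated best with their own number, a hint from the data, not the design. The other deposited table was not run. Signal over background (control AUC 0.902 to 0.938) limits what dim genes can show.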

Other observations

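The values of the averaged contrast given here were computed as chosen before the data were seen. No test was added for them, except that averaged host marker scores were tested above.

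In PGC-1alpha metastases averaged over treatments, several metabolic lists did not shift but held genes that changed in both directions. Over all genes 24.6 percent passed in this contrast, 1760 higher and 2071 lower, so members passing in both directions are no mark of these lists. In the integrated stress response (median 0.01, adjusted p = 0.742) 4 members were higher and 4 lower over all genes, and 5 higher and 4 lower adjusted over the list alone: the serine and one-carbon genes Phgdh (0.57) and Shmt2 (0.55) and the stress sensor Sesn2 (0.51) rose, and the cystine transporter gene Slc7a11 fell. In fatty acid synthesis (−0.23, adjusted p = 0.3), Acacb (0.40), whose product restrains fatty acid entry into mitochondria, and Acly (0.27) rose while the elongase gene Elovl1 (−0.51) and the desaturase gene Scd1 fell (3 higher and 5 lower over all genes, 3 and 6 adjusted over the list alone). Antioxidant defence (−0.06, adjusted p = 0.572) had 2 higher, the glutathione genes Gclc (0.36) and Gpx4 (0.33; not passing without control_phenformin 2, 0.28, or 4, 0.29), and 2 lower over all genes, among them Sod1 (−0.31), on chromosome 16, and 2 and 3 adjusted over the list alone. In the folate cycle and purine list (0.02, adjusted p = 0.834), Umps (−0.74), on chromosome 16, fell and Dhodh (0.38), which acts at the inner mitochondrial membrane in the same pathway, rose (2 higher and 4 lower over all genes and adjusted over the list alone).

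The epithelial list did not shift averaged over treatments (median −0.13, adjusted p = 0.172). Of its 17 genes 3 were lower over all genes, where the share over all genes would give 2.3, and 3 adjusted over the list alone: the keratin gene Krt19 (−0.54), the claudin gene Cldn7 (−0.60) and E-cadherin, Cdh1 (−0.30). The Cdh1 call was lost without any 1 of 9 arrays (−0.30 to −0.25): PGC1a_phenformin 1, 2 or 5, PGC1a_PBS 2 or 6, control_phenformin 3, 4 or 5 or control_PBS 5. Mesenchymal genes did not shift (0.06, adjusted p = 0.886; 1 higher and 2 lower over all genes and adjusted over the list alone), and the transcription factor genes Zeb1 (−0.41) and Snai2 (−0.40, on chromosome 16) fell as well. Snai2 was lost without any 1 of 11 arrays (−0.39 to −0.35): PGC1a_phenformin 2, 3 or 4, PGC1a_PBS 1 or 2, control_phenformin 1, 2 or 3 or control_PBS 3, 4 or 5. The autophagy genes Becn1 (0.38) and Tfeb (0.32) rose while Gabarapl2 (−0.46) fell (lysosome and autophagy list 0.03, adjusted p = 0.671; 4 higher and 3 lower over all genes, 4 and 4 adjusted over the list alone). Among macrophage markers (adjusted p = 0.742), the mannose receptor gene Mrc1 (0.62) rose and the scavenger receptor gene Msr1 (−0.60) fell, 1 each over all genes and 1 each adjusted over the list alone. The lymphocyte granule genes Nkg7 (−0.58) and Gzma fell, in a T and NK list at −0.18 (adjusted p = 0.262; 2 lower over all genes and adjusted over the list alone).

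Normal lung scores were 0.23 ± 0.27 in control metastases under PBS, 0.18 ± 0.40 in control metastases under phenformin, −0.33 ± 0.10 in PGC-1alpha metastases under PBS and −0.01 ± 0.35 in PGC-1alpha metastases under phenformin. Under PBS the lowest control score (−0.098) lay above the highest PGC-1alpha score (−0.220). Club and ciliated scores reached 2.94 in 1 PGC-1alpha array under phenformin, where the group mean was 0.36 ± 1.52.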
